A study of Arabidopsis thaliana with 4 samples.

How the data were processed

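Chromatin immunoprecipitation (ChIP) on tiling arrays was used to measure trimethylated histone H3 at lysine 36 (H3K36me3) in Arabidopsis thaliana seedlings of the Col-0 accession. Per the labels' protocols, untreated seedlings were grown in liquid medium for 10 days or a little longer and the ChIP used a commercial antibody to H3K36me3. DNA from the ChIP and input DNA were labelled with Cy5 and Cy3 and hybridised together. There were 2 pairs of ChIP and input extracts, and each pair was hybridised on 2 arrays with the dyes exchanged, which gave 4 arrays. The labels number the extract pairs I and II, written here as replicates 1 and 2. Nothing in the labels says whether the pairs came from separate cultures, so the p-values measure only the spread between these 2 extract pairs, which may be technical.

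The table that the authors deposited holds 1 log ratio per probe and array. The base of the logarithm, the direction of the ratio and the normalization are not given in the sources used here. Scanner settings, background correction and genome build are not given in the sources used here either. Both arrays of a dye-swap pair hold identical values at all 21685 probes with a value, which would follow from combining the dye swap before deposit or from entering the values of 1 array under both; the sources used here do not say which. Each pair was therefore counted as 1 replicate, n = 2, and no dye effect could be estimated or ruled out. The deposited ratios were not centred: their median was -1.22 in replicate 1 and -1.10 in replicate 2. The identical values do not show which of ChIP and input is the numerator. Ratios are therefore described as deposited, and no direction is assigned to the mark. All sizes are in units of the deposited log ratio, and no fold enrichment is given because the base is unknown. The number of arrays limits the precision.

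Of 21800 identifiers, 115 have no value. Among these, 39 have names without a plate-and-well form, such as control names, and 76 have the plate-and-well form of the other probes. Every probe with a value is identified by a plate set (TA, TB, TC, TD or PD), a plate number and a well from A01 to H12, a layout of 8 rows and 12 columns. No table used here pairs these identifiers with genes or positions. The comparisons by annotation class, by position in the gene, along the chromosome and in 7 gene lists holding 98 genes, all fixed before the data were examined, were therefore not made, and no gene is named.

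Each replicate was centred on its median. The mean of the 2 replicates was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 replicates leave 1 residual degree of freedom, to which the prior over all probes added 23.1. A probe called above or below thus differs from the array median, which is itself a property of what the array tiles, and not from an absence of the mark. The test was checked on simulated data with 21685 probes, 2 replicates, the spread of the real fit and 200 shifted probes. It recovered 11.9% of probes shifted by 0.5, 97.0% of those shifted by 1 and 100% of those shifted by 2, and 3.47% of its calls were false. Recovery depends on how many probes are shifted. With 15440 shifted, the number called in the data, it recovered 89.9% of probes shifted by 0.5, and 1.60% of its calls were false. This second simulation was added after the calls were seen. Both simulations drew each probe independently, with shifts of 0.5, 1 and 2 in nearly equal numbers. In the data the replicate difference was correlated between probes with neighbouring identifiers, so these rates may not hold there.

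Probes were also divided into populations with a mixture of 2 normal distributions fitted to the replicate mean (scikit-learn 1.9.0). A probe belonged to the upper population when its posterior probability was above 0.99 and its value lay above the mean of the lower component. A probe belonged to the lower population when the lower component was the more probable or its value lay below that mean. This division was planned as an alternative to the test. Its use along the identifier order was chosen after the values were seen. Identifiers were ordered by plate set, plate and well, row by row. Pearson correlations were computed over pairs of probes a given number of identifiers apart, across row and plate ends. Their chance level came from 100000 shuffles of the probes within plates. Runs of consecutive upper probes were compared with 100 such shuffles. The mixture weights, the correlation of consecutive probes and the match of an order to a chromosome were checked on simulated data with known answers.

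The rule for named probes, fixed before the data were examined, allows 2 identifiers at each end when no gene can be named: those with the highest and lowest mean among probes past the threshold with the same sign in both replicates. The alternatives were no centring, quantile normalization, eBayes with trend and robust settings, a minimum size of 0.5 (treat), a threshold of 0.01, the mixture, all signs turned and leaving out each replicate. In the closing section, the identifier order was set against the coverage by protein-coding genes and pseudogenes of each chromosome, taken from a RefSeq gene table of the TAIR10.1 assembly. That table was used for this comparison alone, with gene coordinates read only to compute coverage, and no probe was assigned a position or gene from it.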

Results

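The data collected were 2 replicate profiles of H3K36me3 against input DNA over 21685 array probes, each deposited with identical values for 2 arrays with exchanged dyes. H3K36me3 is a histone modification known in plants from the bodies of transcribed genes. The series title places the profile within a reference epigenome of Arabidopsis seedlings, and the question put to the data was which tiles carry the mark. The deposited log ratios ran from -3.41 to 2.76 in replicate 1, with an SD over probes of 1.15, and from -3.49 to 2.36 in replicate 2, with an SD of 1.04. In replicate 1, 25.8% of the probes had a ratio above 0 as deposited, against 25.3% in replicate 2.

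The probes fell into a large population of low log ratios and a smaller, broad population of high ones. The direction of the ratio is not given, so high and low refer to the ratio as deposited. If it runs input over ChIP, every high and low, above and below is exchanged for the mark, including the 2 ends of the probes named below. In the mixture of 2 normal distributions, the lower component was centred at -0.31 relative to the array median, with an SD of 0.37 and a weight of 61.9%. The upper component was centred at 1.58, with an SD of 0.81 and a weight of 38.1%. With a posterior above 0.99, 6137 probes (28.3%) belonged to the upper population, and their ratio averaged 1.94 ± 0.57 (SD over probes). This share depends on the number of components and on the cut-off. With 3 components, which had the lower Bayesian information criterion (53919 against 54494), every probe was assigned to a component. The upper of these alone held 15.6%. With 2 components and a posterior above 0.5, the share was 36.2%. The lower population held 13839 probes (63.8%) with a mean of -0.31 ± 0.36, and 1709 probes (7.88%) lay between. Fitted to each replicate alone, the upper population held 5915 probes in replicate 1 and 5616 in replicate 2. Of these, 5374 were shared, where independent lists of these lengths would share 1532 on average.

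**Figure D1:**
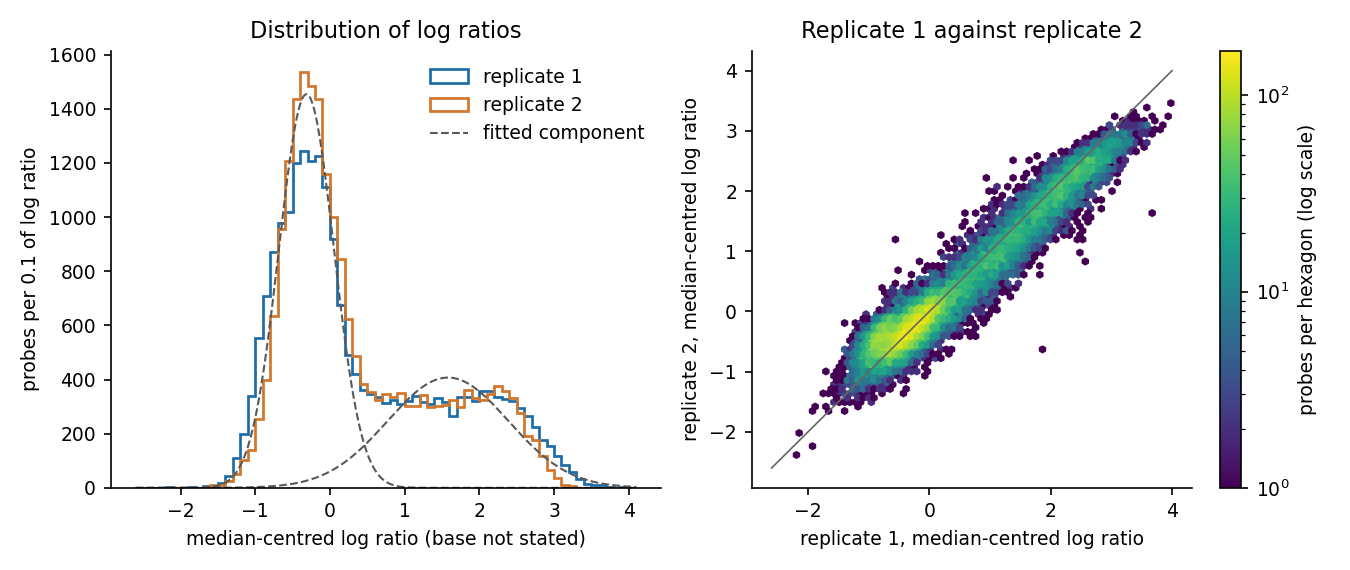
Left: number of probes (per 0.1 of log ratio) against the median-centred log ratio in each replicate, with both normal components fitted to the replicate mean as dashed lines; right: replicate 2 against replicate 1, with hexagons coloured by the number of probes and the line of equality. The peak near -0.31 holds most probes, a broad shoulder extends above it, and the replicates lie along the line with Pearson r = 0.968.

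The test of each probe against the array median gave 8445 probes (38.9%) with a higher ratio and 6995 (32.3%) with a lower ratio (limma, n = 2, Benjamini-Hochberg adjusted threshold of 0.05). The remaining 6245 probes (28.8%) did not pass. The smallest called mean was 0.31 in size, and 15429 of the called probes had the same sign in both replicates. All probes of the upper population were called above (100%), and 50.5% of the lower population were called below. Both divisions use the same replicate mean, and upper probes began at 0.98, so the 100% is not independent of the cut-offs. The median lay inside the lower population, so the calls depend on the centring. Against 0 as deposited, 4542 probes (20.9%) were above and 15090 (69.6%) below, and the share of calls that were above was 23.1% in place of 54.7%. With a minimum size of 0.5 (treat), 6685 probes were above and 1054 below.

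The highest ratio was found at probe TB53E01, with a mean of 3.72 ± 0.37 relative to the array median (SD, n = 2; limma adjusted p = 5.91e-15). It was followed by TA67E12 at 3.57 ± 0.52 (SD, n = 2; limma adjusted p = 5.91e-15). Both were flanked by high probes. The identifiers on either side of TB53E01 had means of 2.36 and 2.55, and those on either side of TA67E12 had means of 2.90 and 1.63. The lowest ratio was found at TA06C05, with -2.29 ± 0.14 (SD, n = 2; limma adjusted p = 1.62e-13), and at TA56G11, with -2.07 ± 0.20 (SD, n = 2; limma adjusted p = 1.32e-12). TA06C05 lay beside another low probe, at -2.05. The identifiers on either side of TA56G11 had means of 0.22 and -0.53, and those 2 identifiers away had -0.99 and -0.01. The SDs above are of each probe's own 2 values. The limma p-values of the 4 named probes rest mostly on the spread over all probes, with standard errors from 0.139 to 0.157.

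The replicates gave nearly the same profile. Across probes, which are not independent of each other, Pearson r was 0.968 and Spearman rho 0.930. The difference between replicates had an SD of 0.298 over probes, which corresponds to 0.211 for a single replicate and 0.149 for the mean of both. It exceeded 1 in size at 43 probes. Pearson r was 0.894 within the upper population, 0.743 within the lower and -0.0087 over the 1709 probes between. These groups were cut by the mean of both replicates, which narrows their range and lowers r, most of all in the narrow group between. The spread over probes in replicate 2 was 0.905 times that in replicate 1.

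Log ratios were similar at probes with neighbouring identifiers. Over 21525 pairs of consecutive probes, the replicate means correlated with r = 0.731, and no shuffle of probes within plates exceeded 0.231 (permutation test, one-sided, p = 1e-05, the smallest that 100000 shuffles can give). The correlation fell to 0.501 at 2 identifiers apart, 0.297 at 5 and 0.137 at 96. Both replicates showed this decline, with 0.735 in replicate 1 and 0.713 in replicate 2 for consecutive probes. The difference between replicates was correlated along the order too, with 0.434 for consecutive probes and still 0.215 at the largest distance computed. Upper probes formed 1759 runs of consecutive identifiers with a mean length of 3.49, where shuffling within plates gave 3840 runs on average. The longest run held 22 probes, against 12.6 on average after shuffling, and 1 of 100 shuffles held a run as long. In all, 80.0% of upper probes lay in runs of 3 or more, and 5.64% stood alone, against 40.7% after shuffling.

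**Figure D2:**
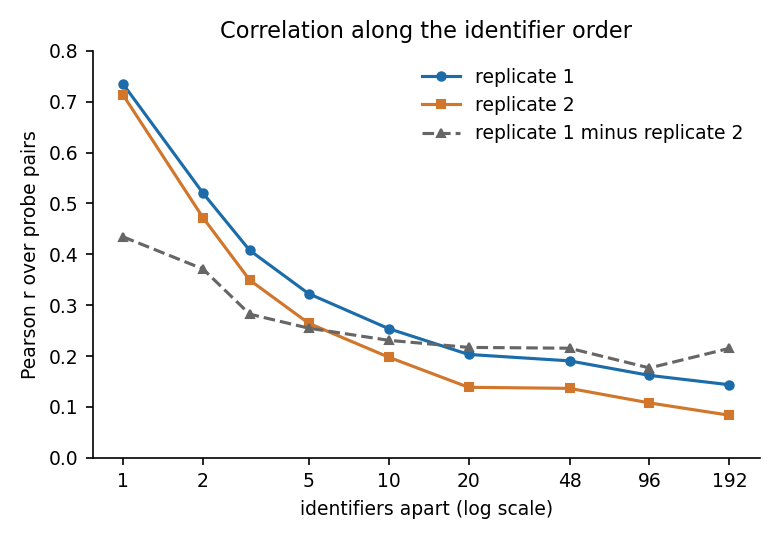
Pearson correlation between probes (vertical axis) against their distance in the identifier order (horizontal axis, log scale), for each replicate and for the difference between replicates. The correlation is above 0.7 for consecutive probes in both replicates and falls to 0.162 and 0.108 at 96 identifiers apart.

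The upper population was unevenly spread over the plate sets. The upper population made up 36.8% of the 9581 probes of set TB, 21.0% of the 9277 probes of set TA and 21.5% of the 2415 probes of set TC. It made up 52.1% of the 96 probes of set TD, a single plate, and 29.4% of the 316 probes of set PD. The mean ratio of set TB was 0.71 in replicate 1 and 0.61 in replicate 2. The corresponding means of set TA were 0.19 and 0.20, so the gap between sets TA and TB was wider than that between replicates. Centring on the median brings the replicates together, so their gap is no measure of error for this difference. Set TC, at 0.14 and 0.21, lay near set TA. Among the 231 plates, the median share of upper probes was 29.2%. The share exceeded 50% on 25 plates and was highest on TC05, at 67.7%.

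Long stretches of plates carried almost none of the upper population. The share was below 5% on 32 plates and 0 on 20 of them. Of these 32, 20 belonged to set TA, 12 to set TC and 0 to set TB. Consecutive plates of this kind formed stretches from TA37 to TA40 (6 upper probes among 296), TA42 to TA47 (6 among 563) and TA49 to TA51 (4 among 288). In set TC they ran from TC17 to TC24 (6 among 732) and from TC27 to TC30 (0 among 324, which allows a share of up to 0.926%). Earlier in set TA, the share was 0 on TA22 and TA23 and 1.04% on TA28. The limit of 0.926% covers counting error alone and takes probes as independent. Upper probes lay in runs and the stretches were chosen by their low share, so it is too narrow.

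**Figure D3:**
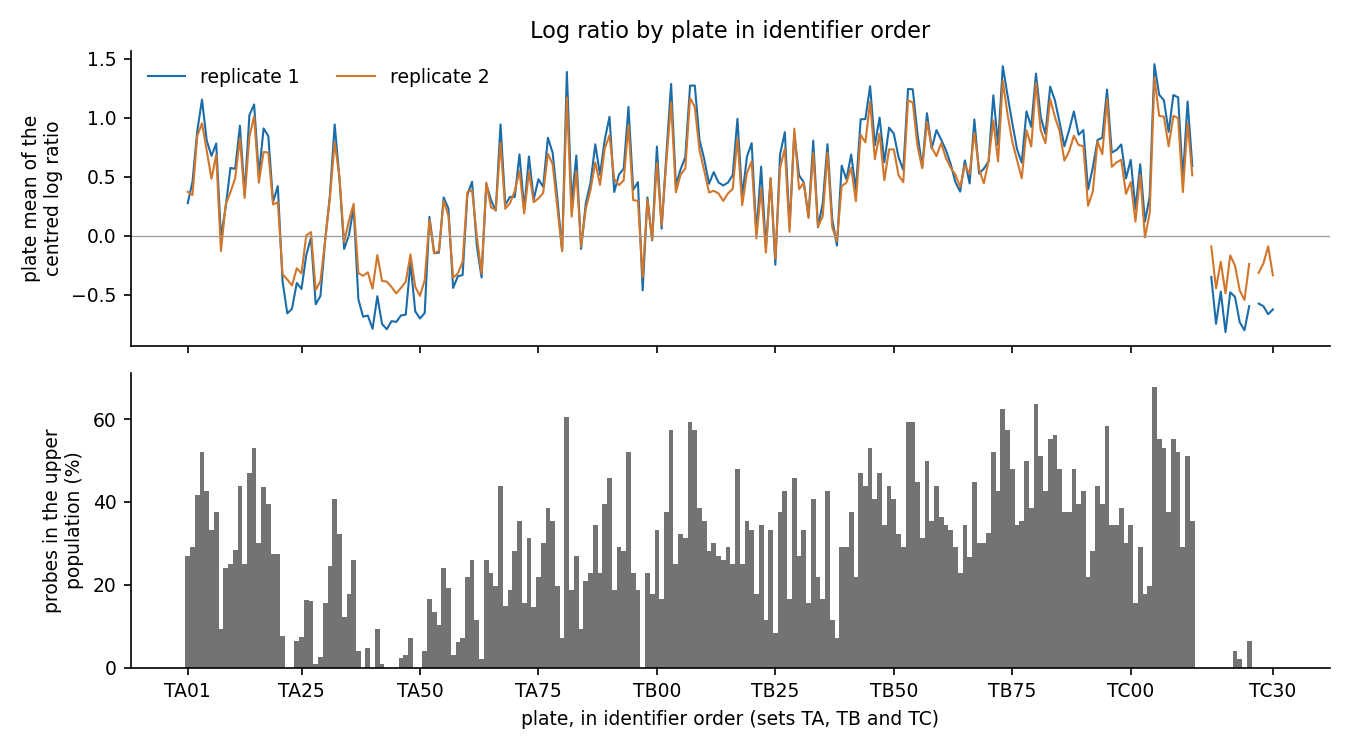
Top: mean median-centred log ratio of each plate in each replicate, in identifier order over sets TA, TB and TC; bottom: percentage of the plate's probes in the upper population. Plates TA37 to TA51 and TC17 to TC30 lie low in both replicates, and lower in replicate 1 than in replicate 2; gaps are plate numbers with no probes.

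The low plates differed from the rest in their low probes as well. Over the lower population alone, the mean ratio on the 32 plates was -0.67 in replicate 1 and -0.40 in replicate 2. On the other 199 plates it was -0.25 and -0.26. The direction was the same in both replicates, and the gap was larger in replicate 1. Over all 2815 probes of the 32 plates, the mean was -0.63 in replicate 1 and -0.37 in replicate 2, against 0.58 and 0.50 on the other plates. On the 32 plates 77.1% of probes were called below the array median and 2.70% above, against 25.6% and 44.4% elsewhere (limma). The plates were chosen by their share of upper probes, so this gap is not independent of that choice.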

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

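Both counts of calls stayed within 1.5 times their value under quantile normalization, eBayes with trend and robust settings and a threshold of 0.01, and turning every sign exchanges them. Without centring, 4542 probes were above and 15090 below, because 0 then lies above the lower population. With a minimum size of 0.5 (treat), 1054 probes remained below and 6685 above, since this test asks for a larger shift. The share of upper probes was 15.6% when the upper of 3 mixture components was taken alone, and between 25.9% and 39.2% under its other settings, which include each replicate alone. The correlation of consecutive probes ranged from 0.656 with plate means taken off to 0.735 in replicate 1 alone. The 4 named probes kept their sign in single replicates, without centring and under quantile normalization. Their means moved without centring, to 2.56 (TB53E01), 2.40 (TA67E12), -3.45 (TA06C05) and -3.23 (TA56G11). Turning every sign reverses the centred means, to -3.72 (TB53E01), -3.57 (TA67E12), 2.29 (TA06C05) and 2.07 (TA56G11). The correlation with chromosome 4 given in the next part fell to 0.569 with all plates. Fits to 4 arrays with a replicate correlation, as independent arrays or with a dye term, and leaving out single arrays, were not run, since both arrays of a pair hold the same values. Leaving out a replicate leaves no residual degree of freedom, so the counts of calls have no such value. Requiring a value on all 4 arrays removes no tested probe. Settings named for the mixture share, the replicate correlation and the identifier order, other than single replicates, were chosen after seeing the data.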

Other observations

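The predictions for the tests below were written before their results were seen, but after the plate profile had been looked at. The bootstraps between orders and the comparison with every sign turned were tests chosen after the results were seen, and without them the prediction for the direction of the ratio would have been met. Beyond the contiguous plates TA01 to TC13, a separate block of 13 plates from TC17 to TC30 held 1133 probes, of which 11 (0.971%) were in the upper population, with a mean ratio of -0.47 relative to the array median. A mixture of 3 normal distributions described the replicate means better than 2 (Bayesian information criterion 53919 against 54494). It put 23.6% of probes in an intermediate population.

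Probes with neighbouring identifiers had similar ratios, and long stretches of plates held few upper probes. The position of a well in its plate was tested with pairs that follow each other in the identifier but sit at opposite ends of a plate. From the last column of a row to the first of the next, r was 0.704 over 1571 pairs (95% interval 0.678 to 0.728, taking pairs as independent), against 0.733 within rows and 0.201 for wells next to each other in a column, which argues against it. A candidate explanation is that the identifiers run along a chromosome. In 200 bins over the 213 contiguous plates, the ratio correlated with protein-coding coverage of chromosome 4 from start to end with r = 0.715. This was the highest of the 10 chromosome and orientation combinations (next, chromosome 2 at 0.597). With all plates, r for chromosome 4 was 0.569, and no ranking of the combinations is given for that setting. Of 199 circular shifts, 0 reached 0.715, the highest giving 0.693. The shifts rotate 1 profile and are not independent of each other, so this count is not a p-value. Shifts of other chromosomes came close, up to 0.676 for chromosome 5. Chromosome 2 from start to end also passed, with 6 of 199 shifts as high. The difference in r between chromosomes 4 and 2 was 0.118 (95% block bootstrap interval 0.037 to 0.236 with blocks of 10 bins, and above 0 with 20 and 40). With pseudogene coverage of chromosome 4, r was -0.677, with 2 of 199 shifts as low, and for chromosome 2 it was -0.619, with 4 of 199. The order was picked by its positive r, which bears on the direction of the ratio only if it would also be picked by size alone. With every sign turned, the best match is chromosome 2 reversed (r = -0.460 as deposited, 5 of 199 shifts as extreme), which passes with protein-coding but not with pseudogene coverage (r = 0.415, 17 of 199). No turned order passed with both, against 2 orders as deposited. In size, r for chromosome 4 exceeded it by 0.254, with block bootstrap intervals of 0.061 to 0.403 (blocks of 10 bins), 0.027 to 0.425 (20) and -0.020 to 0.471 (40). Since the last includes 0, the direction stays open. Coverage and ratio share a broad shape, so single probes cannot be placed from this, and where spots lay on the slide was not tested.

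The replicates differed by region: on the 32 plates with under 5% upper probes, replicate 1 lay 0.26 below replicate 2, and on the other plates 0.08 above it. A difference in scale between replicates was tested by quantile normalization and matching on the mean ratio. The regional difference was -0.337 without matching and -0.262 with matching alone. Quantile normalization as well left it at -0.262 (95% bootstrap interval over plates -0.309 to -0.216), below 0 in 14 of 14 bins. This argues against scale as the whole cause. A plate batch alone would leave no correlation within plates. After the plate mean was taken off, the correlation of the replicate difference at consecutive probes fell from 0.434 to 0.260 (0.247 to 0.272). Plates alone thus did not account for the correlation along the order. A difference in scale was not taken off in this test, so the remaining 0.260 may include it. The spread in replicate 2 was 0.905 times that in replicate 1. The replicate difference averaged 0.174 in the upper population and -0.046 in the lower, so it followed the ratio. Taking off the plate mean also removes the regional difference itself, so this test cannot show whether a plate batch caused it. A plate batch as the cause of the regional difference stays open. A difference between the chromatin samples, a regional difference in background of the ChIP and a layout effect finer than the plate also remain open and were not tested. Lower-population probes averaged -0.67 on the 32 plates against -0.25 elsewhere in replicate 1, and -0.40 against -0.26 in replicate 2. The size of this gap may therefore differ with the replicate, while its direction was shared.

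Lower, intermediate and upper probes are in this paragraph those assigned by the mixture with an intermediate population. These groups held 13189, 5117 and 3379 probes, in that order. They differ from the lower and upper populations used before, which held 13839 and 6137 probes. Intermediate probes may be tiles at the edges of segments of upper probes. Of 5082 such probes with both neighbours measured, 16.1% had 1 upper and 1 lower neighbour (95% Wilson interval 15.1 to 17.1), against 12.2% of upper and 3.87% of lower probes. This was higher than in either population but short of the doubling predicted for edges against upper probes, though not against lower ones, so edges cannot be told apart from segments of intermediate ratio: 23.1% of intermediate probes lay between 2 others of their kind.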
